A study of Homo sapiens with 8 samples.

How the data were processed

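RNA sequencing libraries of total RNA from 4 established human thyroid cancer cell lines were analysed, 8 libraries in all. BHT-101 and FTC-133 cells carried either a control siRNA or an siRNA against SREBF1, and 8505C and K1 cells carried either an empty vector or a vector that overexpresses SREBF1. Each line had 1 library per condition. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with standard Illumina chemistry. Per the submitters' processing notes, FastQC, Trimmomatic 0.38 and featureCounts 2.0.0 were used with the GRCh38 build. The aligner, the annotation release, the strand setting of the counting and the time between transfection and harvest are not given in the sources used here.

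The deposited table holds TPM for 58884 genes by Ensembl identifier, and each library sums to 1000000. In this unit the authors divided reads by gene length and scaled each library to the same total; the lengths used are not given in the sources used here. TPM removes the sequencing depth, so a gene's value is a share of the RNA measured in its library and moves when other genes take more or less of it. Mitochondrial genes took 21.8 to 25.0% of TPM per library and the 10 most abundant genes took 18.1 to 22.4%. All columns of the table were assigned to samples by their names. Gene symbols were matched for 58472 identifiers. Coordinates, gene types and exon lengths were taken from GENCODE release 29, which is on GRCh38, and positions count from 1.

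Depth was recovered after the values had been seen. Where TPM is made from whole reads, TPM multiplied by the exon length of a gene is a whole multiple of a constant of the library. With the GENCODE release 29 exon lengths, 88.7 to 90.9% of values of up to 200 reads came out within 0.05 reads of a whole number, against 9.39 to 10.4% when the lengths were exchanged at random between genes. All of a gene's tested values were whole for 29514 of 33383 genes. In units of 1000000, the recovered reads summed to 19.9 and 21.5 in the control siRNA and SREBF1 siRNA libraries of BHT101, 30.1 and 22.5 in those of FTC133, 16.0 and 15.8 in the empty vector and SREBF1 vector libraries of 8505C, and 22.3 and 29.3 in those of K1. For genes with recovered reads, the ratio of the treated to the control library of a line is given with an exact Clopper-Pearson 95% interval. Such intervals cover counting error within these libraries only, since reads are not independent molecules, and say nothing of how another culture of the line would differ. Genes without recovered reads, such as CXCL8, NR4A2 and CA2, have no interval.

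The test across genes was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), over the 20704 genes with a mean TPM of at least 1. The fit held the cell line as a block and 1 coefficient each for silencing (SREBF1 siRNA minus control siRNA) and overexpression (SREBF1 vector minus empty vector), with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment, two-sided, at 0.05. It had 2 residual degrees of freedom. All 8 libraries shared 1 estimate of the spread, because the libraries of a single experiment leave 1 residual degree of freedom. A second fit with 1 coefficient for the library with more SREBF1 by design against the one with less covered all 4 lines, with 3 residual degrees of freedom. The difference contrast, silencing plus overexpression, is 0 for a gene that moves equally and oppositely in both experiments. No line had a replicate library, so the p-values of single genes measure the spread of the response between cell lines. The effect of a treatment cannot be separated from the state of a single culture. Log2 changes are on the log2(TPM + 1) scale, which understates changes of low genes.

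The block is the cell line, and the pairing comes from the labels, which put a treated and a control library in each line. Without the block, limma called 0 genes for silencing, overexpression, the 4 lines and the difference, with 84, 110, 100 and 84 genes at an unadjusted p under 0.05.

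There were 28 gene lists with 624 genes, of which 591 entered the fit: fatty acid synthesis, cholesterol synthesis and uptake, SREBP pathway, LXR targets, YAP target signature, Hippo core components, mesenchymal, epithelial, haematopoietic, fibroblast and endothelial markers, thyroid differentiation, proliferation, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, fatty acid oxidation, unfolded protein and integrated stress response, interferon response, NF-kB and inflammatory genes, p53 targets, MAPK output, hypoxia targets, TGF-beta targets, lysosome and autophagy, ferroptosis and antioxidant, ribosomal proteins, and replication-dependent histones. The 27 lists with at least 5 members in the fit were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. At the preset correlation camera compares the members of a list with the other genes and takes them as nearly independent. Its p therefore does not take the cell lines as the replicates. Estimated correlations were higher for many lists. With overexpression they were 0.29 for NF-kB and inflammatory genes and 0.61 for interferon response genes. Both alternatives also rest on the residual degrees of freedom, 2 for an experiment and 3 for the 4 lines, which leaves little power. Lists with low correlations lost their small p too. For fibroblast markers with silencing (correlation 0.04) the unadjusted camera p went from 0.011 to 0.153. For mitochondrially encoded genes with overexpression (-0.01) it went from 0.016 to 0.126. Failing there does not show that a list is unchanged. Within a line, list medians were placed among the medians of 10000 random lists of protein-coding genes matched on mean expression in 20 bins, as a description of those libraries, and genes of at least 2-fold change were counted. Random lists hold unrelated genes, whereas the members of a list can vary together. Many of the 28 lists lay outside their random range in each line, so this alone does not single a list out.

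Groups, tests, lists and alternatives were chosen before the data were examined, and so was the rule for named genes. It takes SREBF1 in every library. For each experiment it takes the 8 higher and 8 lower genes with the largest value of the smaller of both lines' absolute log2 changes, in the same direction, with a mean TPM of at least 5 and a symbol that is not a clone, locus or small RNA identifier. It takes up to 4 members of each list with the largest mean change. It always takes a set of genes fixed by name, of which ACACA, FASN, SCD, HMGCS1, INSIG1, SREBF2, YAP1, CCN1 and CCN2 are given and the others are not reported here. It takes the 3 genes with the highest and the 3 with the lowest change within each line, and for the 4 lines the 5 higher and 5 lower genes with the smallest p that go the same way in all of them. The symbol filter let Y_RNA, mitochondrial tRNA and other short genes with few reads through.

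Alternatives were pseudocounts of 0.1 and 5, no filter and a mean TPM of at least 5, median centring, quantile normalization, empirical Bayes without a trend and with robust priors, no block, the 4 libraries of an experiment alone, and leaving out each cell line. Leaving out a line leaves its experiment with 1 pair of libraries, which its coefficient fits exactly, so the spread comes from the other experiment and the lone pair is assumed to vary like it. The last 3 were added after seeing the data: at least 100 recovered reads on average (10347 genes), protein-coding genes (13559 genes), and limma's voom on the recovered reads of 17925 genes. A count model was never the main test.

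Simulated data were made with counting error on top of a spread between libraries set below the observed one. Shares called in them can therefore be too high. The fit was tested on these data with seeded changes of 1 and 2 on the log2 scale. It called 9.18% and 34.3% of them for silencing (17829 genes, 1 unchanged gene called), 8.16% and 37.4% for overexpression (17825 genes, 3 unchanged genes called) and 39.2% and 56.3% for the 4 lines (17829 genes, 6 unchanged genes called). The list test gave an unadjusted p under 0.05 for 3% of 200 random lists. Genes varied independently in this simulation, so it cannot show how the test behaves for lists whose members vary together. In the real data the estimated correlation was 0.86 for proliferation genes with silencing. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used for the rest.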

Results

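Gene expression was measured by RNA sequencing in 4 established thyroid cancer cell lines, 8 libraries in all, after the level of SREBF1 had been lowered or raised. SREBF1 encodes the transcription factor SREBP1, which drives genes of fatty acid synthesis. BHT101 (BHT-101, an anaplastic carcinoma line) and FTC133 (FTC-133, a follicular carcinoma line) received a control siRNA or an SREBF1 siRNA. The 8505C line (anaplastic carcinoma) and the K1 line (papillary carcinoma) received an empty vector or an SREBF1 vector. Values are the authors' TPM. Recovered reads per library, in units of 1000000, summed to between 15.8 and 30.1. Each line had 1 library per condition, so there is no replicate within a line, and p-values of single genes measure the spread of the response between lines. Those of camera on gene lists compare the members with other genes and, at the preset correlation, take the members as nearly independent. With an estimated correlation camera rests on the few residual degrees of freedom of the fit. A high adjusted p there has little power behind it and does not show that a list is unchanged. Intervals in square brackets are exact 95% intervals for counting error between the libraries of 1 line.

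SREBF1 (ENSG00000072310, a protein-coding gene on the minus strand of chromosome 17 at 17810399 to 17837002, GRCh38) followed the labels in every line. With the siRNA it was at 40.8 TPM against 97.4 in the control of BHT101, a ratio of 0.42 [0.40, 0.44], and at 89.8 against 275.0 TPM in FTC133, a ratio of 0.33 [0.32, 0.34]. With the vector it was at 155.6 against 73.1 TPM in 8505C, a ratio of 2.13 [2.03, 2.24], and at 157.2 against 19.4 TPM in K1, a ratio of 8.12 [7.55, 8.73]. Reads from the vector and from the endogenous gene cannot be told apart in these values. Over the lines, limma gave a log2 change of -1.42 (SE 0.45, adjusted p = 0.964) with silencing and 2.02 (SE 0.45, adjusted p = 0.689) with overexpression, so neither passed over all genes, although the direction was the intended one in 4 of 4 lines.

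The first question was which lipid genes followed SREBF1. In FTC133 the SREBF1 siRNA library held less FASN, the fatty acid synthase (67.5 against 246.3 TPM, ratio 0.274 [0.265, 0.284]), less SCD, the stearoyl-CoA desaturase (313.0 against 803.9 TPM, ratio 0.39), and less ACACA, the acetyl-CoA carboxylase (25.3 against 43.5 TPM, ratio 0.58). INSIG1, which retains SREBPs in the endoplasmic reticulum, was at 160.6 against 354.7 TPM there. In BHT101 the pattern differed. FASN was at 174.9 against 143.8 TPM with the siRNA (ratio 1.22 [1.18, 1.25]), ACACA at 52.0 against 50.4 TPM and SCD at 619.1 against 773.4 TPM (ratio 0.80). Genes of cholesterol synthesis were instead higher, with HMGCS1 at 57.6 against 20.2 TPM (ratio 2.84 [2.58, 3.15]), SQLE at 1458 against 555.5 TPM and MSMO1 at 257.7 against 88.2 TPM. FASN lies on chromosome 17 at 82078333 to 82098332 and SCD on chromosome 10 at 100347124 to 100364834.

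With the vector, SCD was at 1452 against 434.8 TPM in K1 (ratio 3.34 [3.27, 3.41]), with INSIG1 at 349.3 against 234.1 and FASN at 88.0 against 68.8 TPM. The same genes moved little in 8505C, where SCD was at 1204 against 1087 TPM (ratio 1.11), FASN at 132.7 against 128.8 TPM and INSIG1 at 47.2 against 46.1 TPM. SREBF2, the paralog that drives cholesterol genes, was at 155.5 against 139.3 TPM in BHT101 (ratio 1.12 [1.08, 1.16]), 87.6 against 93.1 TPM in FTC133, 79.7 against 98.9 TPM in 8505C and 135.0 against 103.9 TPM in K1. None of these genes passed limma in either experiment.

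**Figure D1:**
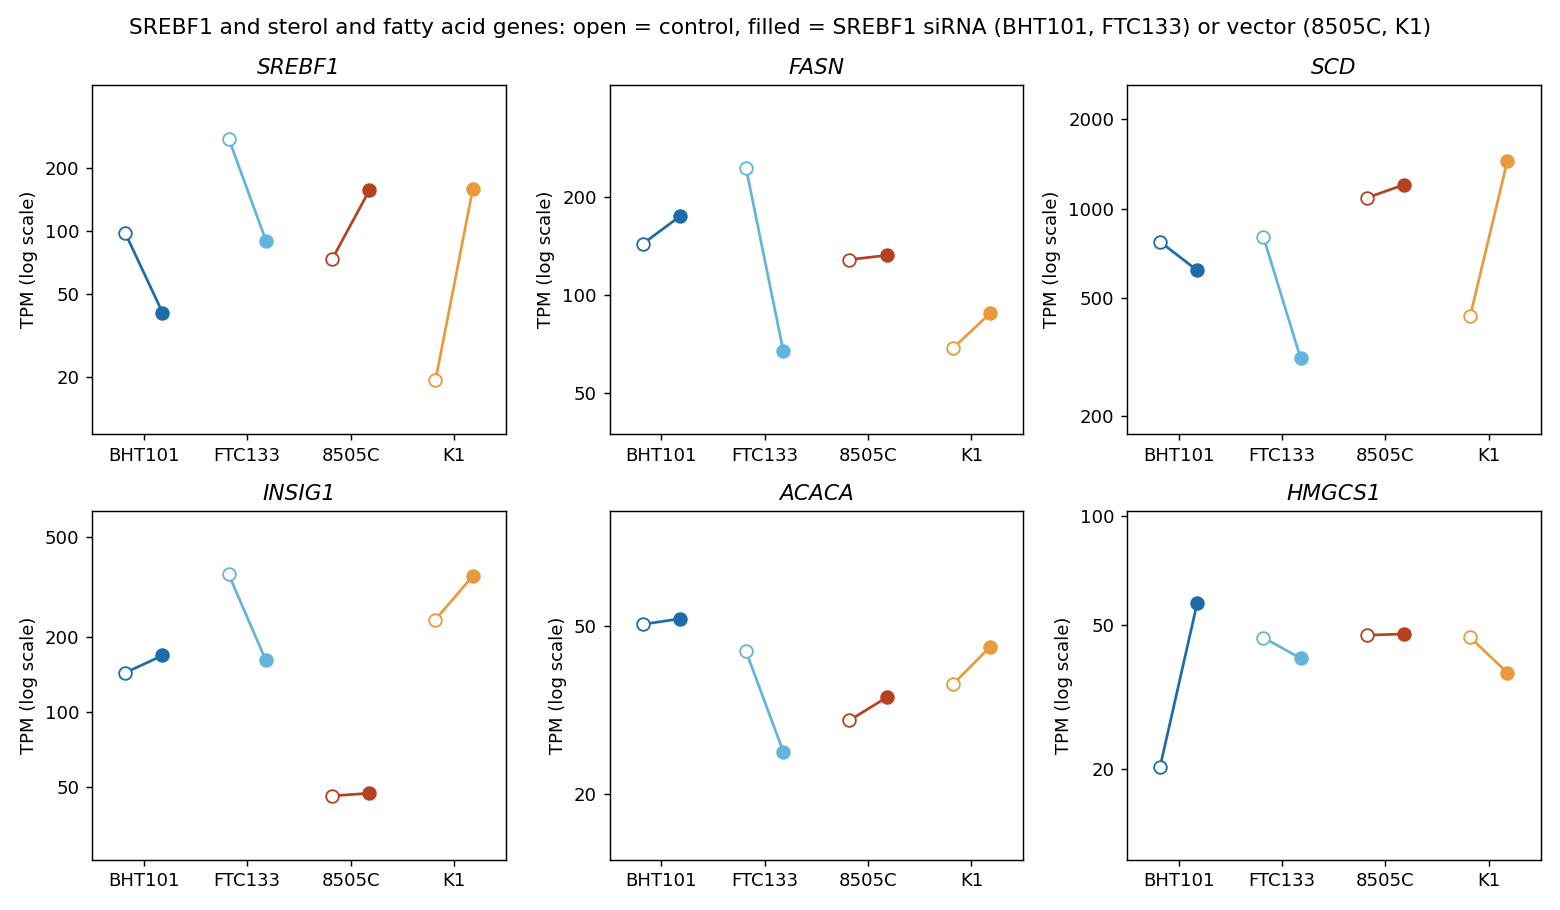
TPM on a log scale of SREBF1 and 5 genes of fatty acid and sterol metabolism in the 4 lines, with open circles for the control siRNA or empty vector library and filled circles for the SREBF1 siRNA or SREBF1 vector library, 1 library each. SREBF1 moved as intended in every line, whereas FASN was lower with the siRNA in FTC133 (67.5 against 246.3 TPM) and not in BHT101 (174.9 against 143.8 TPM).

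Silencing was then compared over BHT101 and FTC133. Fatty acid synthesis genes were lower on balance (19 of 28 below 0, median log2 change -0.20). FADS2, a fatty acid desaturase, was lower in both lines (8.02 against 19.7 and 21.9 against 40.1 TPM), while ACLY, which makes cytosolic acetyl-CoA, was higher in both (300.5 against 197.3 and 419.6 against 146.2 TPM). The list passed camera (adjusted p = 0.0254) but not with an estimated correlation (adjusted p = 0.748). Its median was -0.42 in FTC133, below the 95% range of matched random lists (-0.18 to 0.09), and 0.00 in BHT101, within it, and without FTC133 the adjusted p was 0.854. When a line is left out of an experiment, the experiment keeps 1 pair of libraries that the fit matches exactly, so here and below such a p takes its spread from the lines of the other experiment and assumes that the lone pair varies like them.

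Interferon response genes were higher, with 34 of 34 above 0 (median 0.53, camera adjusted p = 1.67e-08, adjusted p = 0.748 with an estimated correlation). This came from FTC133, where the median was 0.96 (random lists -0.16 to 0.10). There ISG15 was at 408.9 against 102.5 TPM, IFIT1 at 96.8 against 22.2 TPM and IFI6 at 969.7 against 295.1 TPM. In BHT101 the median was 0.08, inside the random range, with ISG15 at 264.8 against 178.0 TPM and MX1 at 9.27 against 9.42 TPM. Without FTC133 the list's adjusted p was 0.788. Hypoxia targets had 19 of 20 members above 0 (median 0.37, camera adjusted p = 0.000197, adjusted p = 0.748 with an estimated correlation), again with FTC133 at 0.79 and BHT101 at -0.05. In FTC133 the carbonic anhydrase gene CA9 was at 143.3 against 31.4 TPM and ANGPTL4 at 104.2 against 23.4 TPM. Without FTC133 this list reversed to a median of -0.05 (adjusted p = 0.788).

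Other lists were led by BHT101. Cholesterol synthesis and uptake had 23 of 28 members above 0 (median 0.25, camera adjusted p = 0.000197), with a median of 0.52 in BHT101 (random lists -0.05 to 0.12) and -0.06 in FTC133. The unfolded protein and integrated stress response had 23 of 28 above 0 (median 0.30, camera adjusted p = 0.00351), with 0.63 in BHT101 and -0.05 in FTC133; its chaperone genes DNAJB9 and HSP90B1 were at 134.6 against 43.5 and 919.9 against 563.4 TPM in BHT101. MAPK output had 14 of 20 above 0 (median 0.15, camera adjusted p = 0.0248), with EGR1 at 46.2 against 18.4 TPM in BHT101 and 23.2 against 14.6 TPM in FTC133. The adjusted p with an estimated correlation was 0.748 for each of these lists. Without BHT101 their medians were -0.06, -0.05 and -0.11, with adjusted p of 0.732, 0.507 and 0.804.

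A further pair of lists passed camera and was higher in both lines. Lysosome and autophagy genes had 20 of 23 members above 0 (median 0.18, camera adjusted p = 0.0039, medians 0.23 in BHT101 and 0.11 in FTC133). With the SREBF1 vector 18 of 23 were above 0 too (median 0.14, camera adjusted p = 0.0825). Their median was then 0.19 in K1 (random lists -0.16 to 0.07) and -0.02 in 8505C, within its range. In K1 this list thus rose with more SREBF1 as well. Fibroblast markers had 10 of 11 above 0 with silencing (median 0.36, camera adjusted p = 0.0376, medians 0.25 and 0.33), among them the collagen gene COL1A2 at 8.54 against 3.16 and 2597 against 2073 TPM. Both lists had an adjusted p of 0.748 with an estimated correlation in the silencing contrast. Without BHT101 their adjusted p was 0.208 and 0.39.

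Among single genes, limma called 0 of 20704 with silencing. The smallest adjusted p was 0.769, and 1002 genes had an unadjusted p under 0.05 where 1035 would be expected with no effect. By voom on the recovered reads the count was also 0, but narrowly, with a smallest adjusted p of 0.05985. There 1234 of 17925 genes had an unadjusted p under 0.05. Besides SREBF1, the genes lower in both lines included RASSF3, of the Ras association domain family (42.3 against 95.5 TPM, ratio 0.44 [0.41, 0.48], and 12.1 against 40.2 TPM, ratio 0.30 [0.27, 0.34]), the claudin gene CLDN7 (9.40 against 21.6 and 3.30 against 8.25 TPM), the nucleosome-binding protein gene HMGN2 (150.8 against 301.2 and 231.8 against 501.6 TPM) and CPNE7 (74.9 against 158.4 and 0.914 against 4.31 TPM). KRT7-AS was at 4.48 against 20.2 TPM in BHT101 and 9.52 against 20.2 TPM in FTC133. It is annotated antisense inside KRT7 on chromosome 12 at 52245048 to 52247448, and KRT7 itself was at 74.4 against 224.4 and 154.7 against 278.2 TPM. With the strand setting not given, reads of this pair cannot be assigned with certainty. Adjusted over the list alone, 2 epithelial markers passed, both lower (CLDN7 and KRT7, adjusted p = 0.0257), against 0 over all genes.

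Genes higher in both siRNA lines included IL1RAP, the interleukin 1 receptor accessory protein (24.1 against 11.3 TPM, ratio 2.14 [1.96, 2.34], and 22.3 against 8.31 TPM, ratio 2.68 [2.46, 2.93]), the hyaluronan-degrading protein gene CEMIP (14.2 against 6.07 and 20.02 against 3.41 TPM), MILR1 (28.1 against 10.9 and 13.3 against 4.34 TPM) and the placental growth factor gene PGF (3.75 against 1.24 and 12.98 against 2.69 TPM). The adjusted p of the genes named so far in these 2 paragraphs lay at 0.964 over all genes. The remaining genes that the selection took rested on few reads. They were MT-TW (adjusted p = 0.769), MT-TM, a Y_RNA gene, COL5A1-AS1 and U4, with at most 32 reads in any of the siRNA experiment's libraries, and the pseudogene PDIA3P2, lower with the siRNA in both lines (7 against 24 and 7 against 30 reads).

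Overexpression was compared over 8505C and K1. NF-kB and inflammatory genes were lower, with 25 of 26 below 0 and a median log2 change of -1.09. The granulocyte growth factor gene CSF3 (chromosome 17, 40015361 to 40017813) was at 1.55 against 20.6 TPM in 8505C, a ratio of 0.08 [0.04, 0.13], and at 102.0 against 1530 TPM in K1, a ratio of 0.07 [0.06, 0.07]. The chemokine gene CXCL1 was at 76.6 against 371.8 TPM and 1138 against 3737 TPM, and IL1B at 25.6 against 247.1 TPM and 2331 against 4621 TPM. IL1A was at 5.42 against 68.7 TPM in 8505C and 400.9 against 505.5 TPM in K1. The list passed camera (adjusted p = 1.00e-15) and did not with an estimated correlation (adjusted p = 0.853). Its medians were -1.23 in 8505C (random lists -0.16 to 0.12) and -0.69 in K1 (random lists -0.16 to 0.06). With 1 vector line left out, the spread came from the siRNA lines alone, and only under that assumption did it pass camera without 8505C (adjusted p = 7.47e-05) and without K1 (adjusted p = 5.64e-12). Adjusted over the list alone, 11 members passed, all lower, among them CSF3 (adjusted p = 0.00196), against 0 over all genes. In the same libraries the leukocyte gene LCP1 was at 17.1 against 76.6 TPM in K1, and 3 of 16 haematopoietic markers exceeded 1 TPM in the empty vector library of K1 and 1 in that of 8505C.

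Other genes lower in both vector lines were IL24, a cytokine gene (25.1 against 88.2 and 229.7 against 1048 TPM), the epithelial transcription factor gene EHF (0.782 against 17.8 and 5.96 against 31.0 TPM), the carbonic anhydrase gene CA2 (1.83 against 15.3 and 17.7 against 82.4 TPM), the orphan nuclear receptor gene NR4A2 (4.02 against 16.1 and 5.08 against 21.04 TPM) and SPANXN4 (5.10 against 37.3 and 0.460 against 16.7 TPM). Genes higher in both included the adhesion gene CADM1 (8.41 against 1.804 TPM, ratio 4.66 [3.66, 6.0], and 12.4 against 4.27 TPM, ratio 2.92 [2.53, 3.37]), SEL1L3 (2.39 against 0.230 and 85.3 against 28.4 TPM) and HLA-DRB1, an MHC class II gene whose reads can be shared with near-identical paralogs (1.40 TPM against a listed 0, and 17.8 against 2.99 TPM). RN7SL239P, 3 Y_RNA genes, MT-TI and UST-AS2 were also taken and rested on at most 26 reads in any of these libraries.

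**Figure D2:**
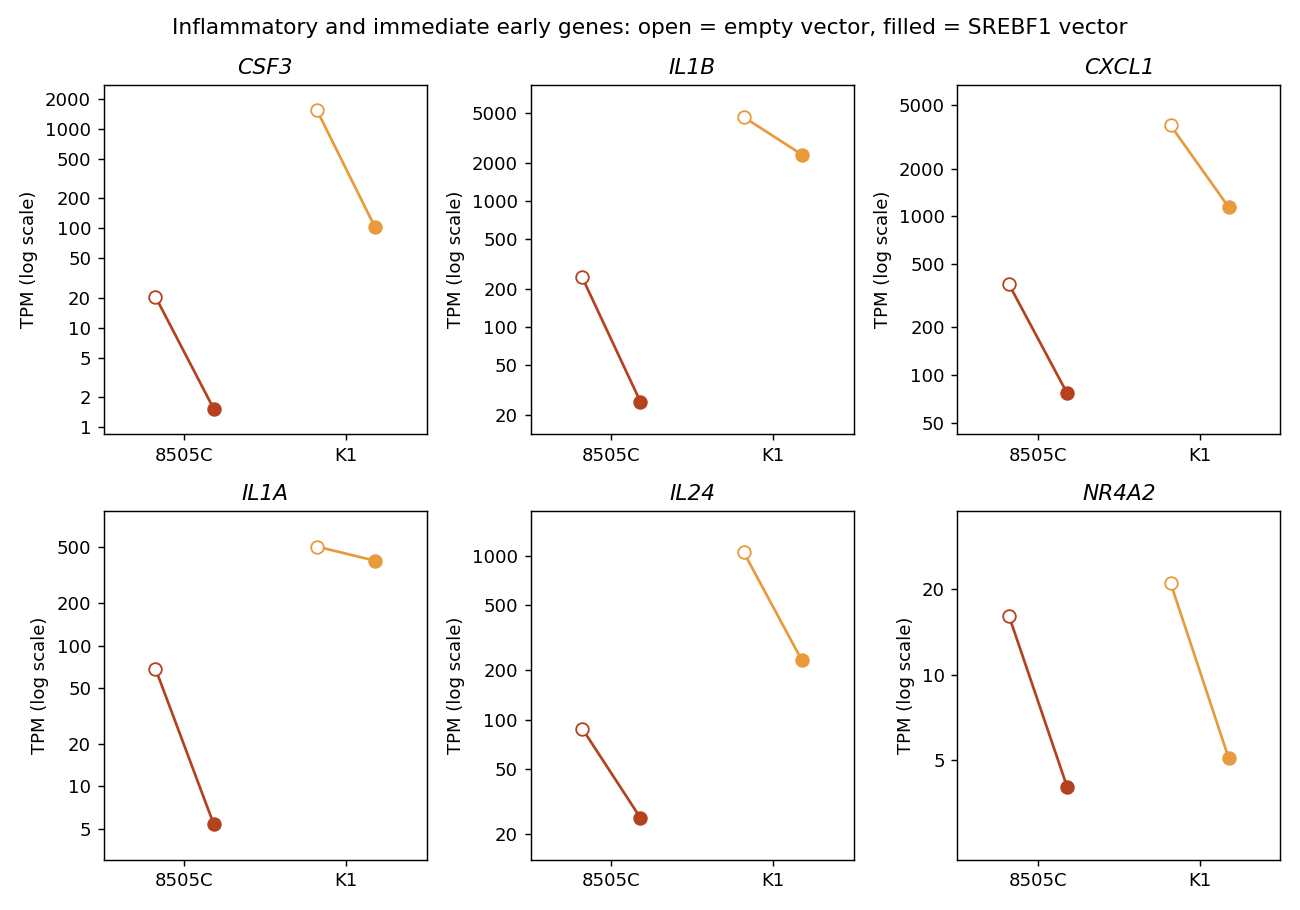
TPM on a log scale of 6 inflammatory or immediate early genes in 8505C and K1, with open circles for the empty vector and filled circles for the SREBF1 vector, 1 library each. All 6 genes were lower with the SREBF1 vector in both lines, CSF3 from 20.6 to 1.55 TPM in 8505C and from 1530 to 102.0 TPM in K1.

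Limma called 0 of 20704 genes with overexpression over all genes (smallest adjusted p = 0.526), and 1188 had an unadjusted p under 0.05. The count differed from 0 under only 2 of the settings tried, both added after the values had been seen. Among the 10347 genes with at least 100 recovered reads, limma called 2, CSF3 (log2 change -3.49, SE 0.25) and the unnamed long noncoding RNA gene ENSG00000280614 (-4.28, SE 0.28), both lower in 2 of 2 lines with an adjusted p of 0.0381. ENSG00000280614 has near-identical copies in ribosomal DNA, so its value is uncertain. By voom on the recovered reads 10 genes were called. Of these, 9 were lower, among them CSF3 (adjusted p = 0.000817), IL24 (0.0339) and CXCL1 (0.0355), and GDF15, a stress-induced cytokine gene, was higher (3.52 against 1.18 TPM in 8505C and 262.1 against 70.9 TPM in K1, adjusted p = 0.0355). GDF15 was also the p53 target that passed adjusted over the list alone (adjusted p = 0.0488), and CD14 the haematopoietic marker (adjusted p = 0.0364, 13.2 against 22.3 and 15.3 against 47.1 TPM). Neither adjustment counts the other lists tried, and the haematopoietic list had 4 members in the fit.

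Further lists passed camera with overexpression. Ribosomal protein genes (27 of 30 below 0, median -0.16, camera adjusted p = 2.82e-05), glycolysis genes (17 of 19 below 0, median -0.33, 8.73e-05), replication-dependent histones (11 of 11 below 0, median -0.51, 0.000293), hypoxia targets (15 of 20 below 0, median -0.27, 0.000979) and oxidative phosphorylation genes (31 of 42 below 0, median -0.08, 0.0285) were lower. Unfolded protein and integrated stress response genes were higher (21 of 28 above 0, median 0.27, 0.0126). The adjusted p with an estimated correlation was 0.853 for every one of them. Within lines, oxidative phosphorylation genes lay inside their random range in both 8505C (-0.10) and K1 (-0.11). So did ribosomal protein genes in K1 (-0.11) and stress response genes in 8505C (0.05). The phosphofructokinase regulator PFKFB3 was at 42.9 against 173.1 TPM in K1 and 47.4 against 56.1 TPM in 8505C, and the linker histone gene H1-2 at 50.0 against 161.3 TPM in 8505C and 26.4 against 40.7 TPM in K1. In K1 the serine synthesis genes PSAT1 and PHGDH were at 401.1 against 41.8 and 84.3 against 18.5 TPM, and the cystine transporter gene SLC7A11 at 85.8 against 9.15 TPM. In 8505C PSAT1 was at 52.99 against 59.3 TPM and SLC7A11 at 6.22 against 6.03 TPM. Without 8505C the ribosomal, histone and oxidative phosphorylation lists did not pass. Their medians were then -0.11, 0.15 and -0.11, against -0.16, -0.51 and -0.08 over both lines, so only the histone median turned. Without K1 the glycolysis, hypoxia, oxidative phosphorylation and stress response lists did not pass. Their medians were then -0.21, -0.25, -0.10 and 0.05, against -0.33, -0.27, -0.08 and 0.27 over both lines. A lost call therefore does not by itself show that a list rested on K1.

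**Figure D3:**
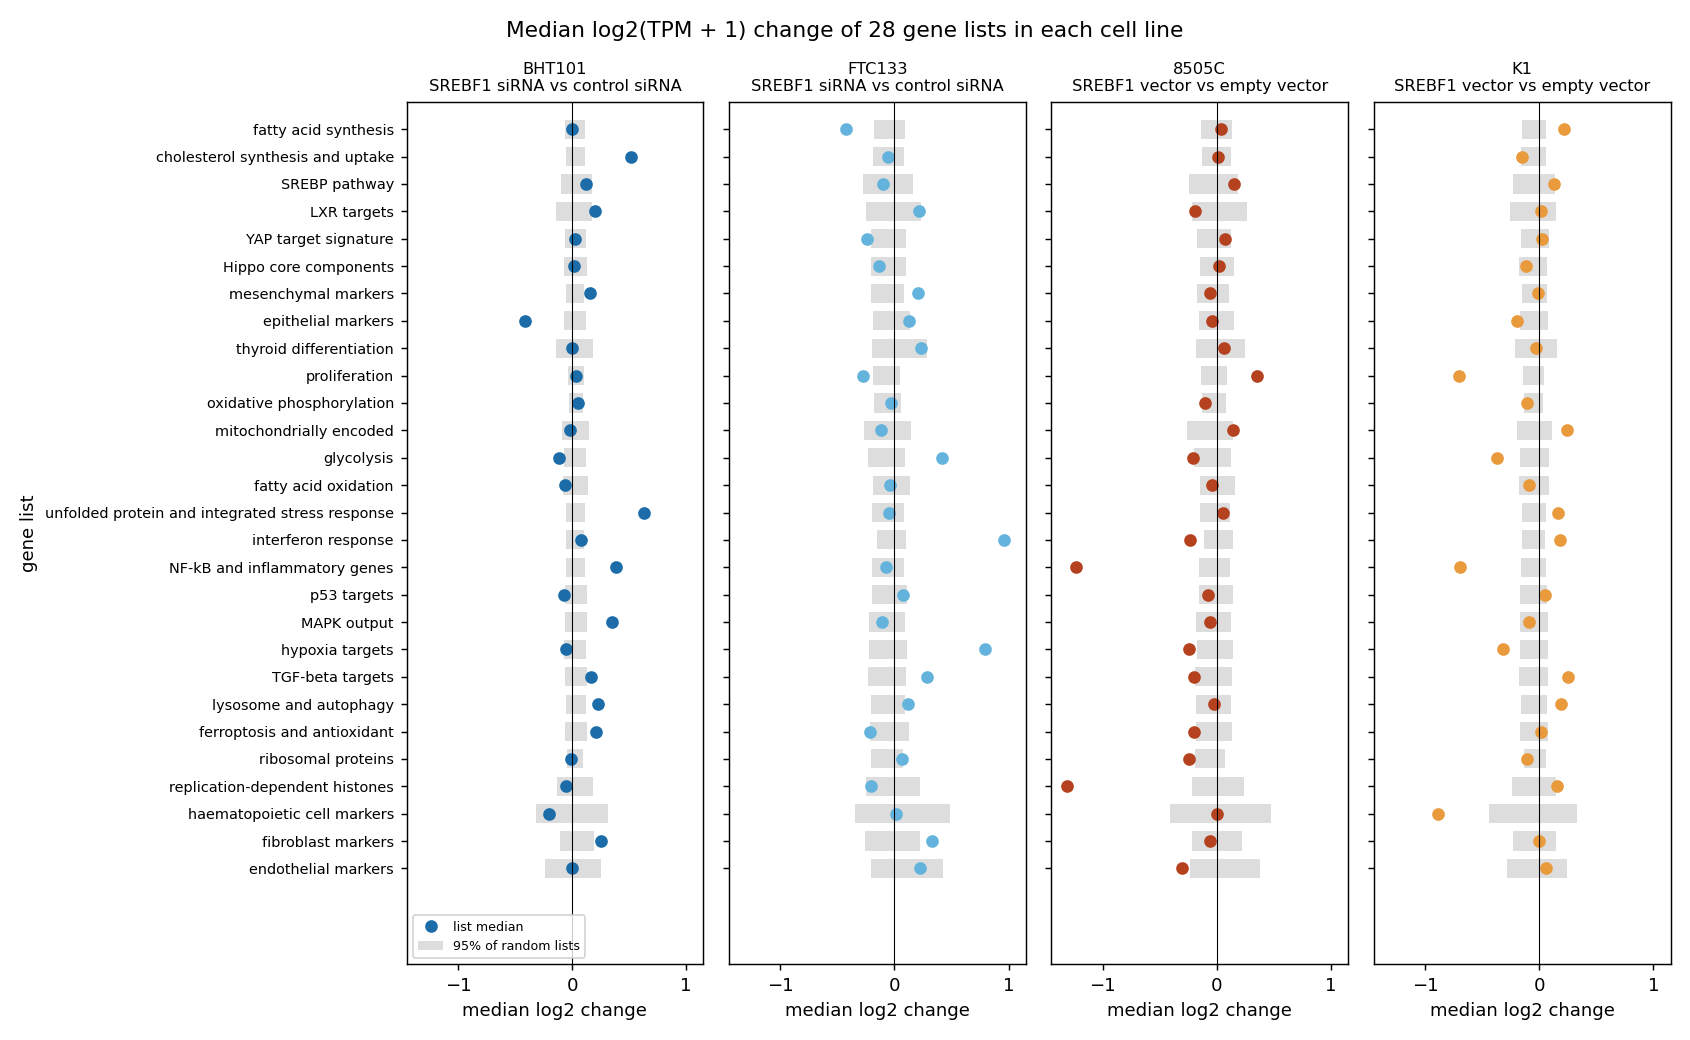
Median log2(TPM + 1) change of the members in the fit of 28 gene lists in each line, as points, with grey bars for the central 95% of medians of 10000 random lists matched on mean expression. NF-kB and inflammatory genes lay below the bars in both vector lines (-1.23 in 8505C and -0.69 in K1), and interferon response genes above them in FTC133 (0.96) and K1 (0.18), within them in BHT101 (0.08) and below them in 8505C (-0.23). Many other lists also lay outside the bars in each line.

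Across all 4 lines, the library with more SREBF1 by design was compared with the one with less. Limma called 0 of 20704 genes (smallest adjusted p = 0.936, 930 with an unadjusted p under 0.05), and voom called 1, CSF3 (adjusted p = 0.000504), which was nearly absent from the siRNA lines (0.444 TPM or less) and so rested on the vector lines. Genes that went the same way in all lines included NAMPT, the rate-limiting enzyme of NAD salvage, lower wherever SREBF1 was higher (log2 change -1.0, SE 0.16). It was at 306.2 against 120.5 TPM with the siRNA in BHT101 and 264.3 against 146.2 TPM in FTC133, and at 235.6 against 336.4 TPM with the vector in 8505C and 186.9 against 463.9 TPM in K1. The tissue factor gene F3 (-0.95, SE 0.18), the parathyroid hormone-related gene PTHLH (-1.09, SE 0.19), IFITM3 (-0.39, SE 0.07) and PPIF (-0.51, SE 0.10) also went against SREBF1. The protease gene PRSS23 (0.61, SE 0.09) and the myosin gene MYO6 (0.38, SE 0.08) went with it, as did the pseudogenes SNRPGP4 and PDIA3P2, which had at most 30 reads in a library. Each of these genes had an adjusted p of 0.936. Adjusted over the list alone, F3 passed within the YAP target signature (adjusted p = 0.0492). That adjustment does not count the other lists tried, and F3 went against the signature, in which 17 of 22 members were above 0.

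As a group, hypoxia targets were below 0 in 20 of 20 members (median -0.30, camera adjusted p = 1.26e-07), NF-kB and inflammatory genes in 24 of 26 (-0.55, 6.46e-11) and glycolysis genes in 16 of 19 (-0.23, 3.76e-05). The adjusted p with an estimated correlation was 0.579 for these lists, and each passed camera whichever line was left out, with medians that then ranged from -0.41 to -0.16 for hypoxia targets (nearest to 0 without FTC133), -0.86 to -0.35 for NF-kB and inflammatory genes (without 8505C) and -0.31 to -0.17 for glycolysis genes (without K1). For each list 1 siRNA line went against this, with a median below 0 where SREBF1 was lowered: hypoxia targets (-0.05) and glycolysis genes (-0.11) in BHT101, and NF-kB and inflammatory genes (-0.07) in FTC133. Fatty acid synthesis genes were above 0 in 20 of 28 members (median 0.09, camera adjusted p = 0.0203, 0.579 with an estimated correlation), and cholesterol genes below 0 in 22 of 28 (-0.15, 0.00126, adjusted p = 0.593 with an estimated correlation). The fatty acid list did not pass without FTC133 (adjusted p = 0.362) or K1 (0.135), nor the cholesterol list without BHT101 (0.538). Interferon response genes were below 0 in 30 of 34 (-0.27, camera adjusted p = 0.000147, 0.619 with an estimated correlation, 0.944 in camera without FTC133). Without K1 their median was -0.44, since in K1 they were higher with the vector (24 of 34 above 0, median 0.18, random lists -0.15 to 0.05). Ribosomal protein genes (median -0.09, camera adjusted p = 0.000919, 0.593 with an estimated correlation), histones (-0.28, 0.0155, 0.619 with an estimated correlation), MAPK output (-0.25, 0.027) and fibroblast markers (-0.28, 0.027, both 0.579 with an estimated correlation) were also below 0. The ribosomal and histone lists did not pass without 8505C (adjusted p of 0.307 and 0.415), MAPK output without BHT101 (0.532), nor fibroblast markers without BHT101, FTC133 or 8505C (0.102 to 0.197). In those fits the medians were -0.03 for ribosomal protein genes and -0.0048 for histones. They changed less for MAPK output (-0.21) and fibroblast markers (-0.32 to -0.24). YAP1 and its targets CCN1 and CCN2 did not move alike. YAP1 was at 67.5 against 71.1 TPM in BHT101, 72.3 against 81.3 TPM in FTC133, 140.6 against 138.1 TPM in 8505C and 241.1 against 268.1 TPM in K1. CCN1 was at 561.5 against 951.3 TPM in FTC133, 42.5 against 47.6 TPM in BHT101, 713.3 against 288.5 TPM in 8505C and 1499 against 1631 TPM in K1. CCN2 was at 47.6 against 118.2 TPM in FTC133 and 53.1 against 40.8 TPM in BHT101, and higher with the vector in both 8505C (718.4 against 432.9 TPM) and K1 (859.3 against 589.6 TPM). The YAP target signature had 17 of 22 members above 0 and did not pass (camera adjusted p = 0.0775).

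The last contrast asked whether the effects of silencing and overexpression departed from equal and opposite. Limma called 0 of 20704 genes (smallest adjusted p = 0.869, 1123 with an unadjusted p under 0.05), and voom also called 0. The median SE of a gene was 0.36 on the log2 scale in this contrast, 0.26 for silencing or overexpression and 0.18 over the 4 lines.

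Within lines, changes of at least 2-fold were described without a test. They numbered 1270 genes in BHT101, 1597 in FTC133, 1982 in 8505C and 1665 in K1, and among genes with at least 100 recovered reads 60, 216, 283 and 222. In 8505C the cytokine gene IL33 was at 1.06 against 105.7 TPM with the vector (K1, 5763 against 5679 TPM), the amino acid transporter gene SLC6A14 at 3.94 against 170.5 TPM, the kinase gene STK26 at 43.1 against 1.33 TPM, and EPDR1 at 19.0 TPM (223 reads) against 0 reads. In K1 the osteopontin gene SPP1 was at 30.6 against 0.834 TPM and IGFBP3 at 319.8 against 30.3 TPM, whereas IGFBP3 was at 199.9 against 564.3 TPM in 8505C. In FTC133 the kinase gene NUAK2 was at 20.2 against 82.3 TPM. The extremes of BHT101 were RNA5-8SN1, Y_RNA genes, TRBJ2-2P and MT-TS1, with at most 23 reads each in its libraries. The other extremes of FTC133, 8505C and K1 were noncoding genes, gene segments and pseudogenes with at most 117 reads in a library.

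The measured changes of the lines of an experiment had little in common. Each change is between single libraries, and their noise, which was not estimated, lowers such correlations. Low values therefore do not show that the responses differ. Among the 10347 genes with at least 100 recovered reads, the log2 changes of BHT101 and FTC133 had a Pearson correlation across genes of 0.19 (Spearman 0.18) and those of 8505C and K1 of 0.04 (Spearman 0.00448). Over all 20704 genes the correlations were 0.0255 (Spearman 0.0746) and 0.0205 (Spearman 0.0112). Pairs of an siRNA line with a vector line had Pearson correlations of -0.045 to 0.0039 among genes with at least 100 recovered reads. Beside these the siRNA lines stood higher, and the vector lines did so little. Genes are not independent replicates, so no p-value is given. Changes of at least 2-fold were shared by 5 higher and 4 lower genes between the siRNA lines (0.505 and 0.166 by independent lists) and by 6 higher and 17 lower genes between the vector lines (1.09 and 2.02). Changes of at least 2-fold in opposite directions also exceeded that expectation, at 1 and 1 gene between the siRNA lines (0.309 and 0.272) and 3 and 4 between the vector lines (1.59 and 1.37), so independent lists expect too few shared genes here.

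**Figure D4:**
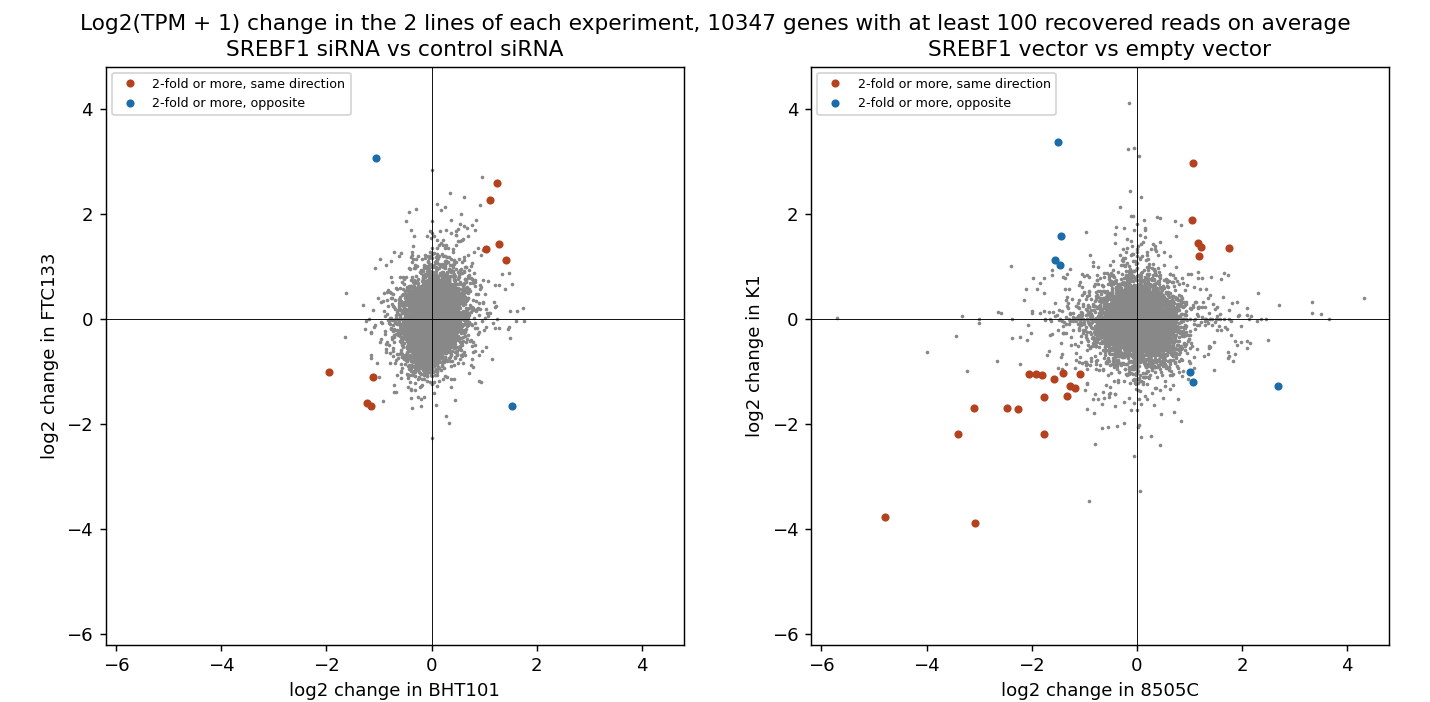
Log2(TPM + 1) change per gene in the 2 lines of each experiment, for the 10347 genes with at least 100 recovered reads on average, with coloured points for genes of at least 2-fold change in both lines. Few genes lie far out on the diagonal, and between the vector lines 17 genes were lower and 6 higher in both.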

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

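The test of haematopoietic cells, that of the siRNA itself, that of SREBF2, and the bootstrap intervals were chosen after the results had been seen. The bootstrap resampled the members of a list within 1 pair of libraries, and such members are not independent. Its intervals describe the spread over members and say nothing of how another culture would differ. The following are differences between the lines of an experiment where members or libraries moved in opposite directions, and none of these differences was tested, since each line has 1 library per condition.

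With SREBF1 siRNA, the median log2 change of glycolysis genes was 0.42 in FTC133 and -0.11 in BHT101, a difference of 0.529. That of ferroptosis and antioxidant genes was -0.21 in FTC133 and 0.21 in BHT101, a difference of -0.425. The 4 medians lay outside or at the edge of their random ranges. SIRLNT was at 14.5 against 47.9 TPM in FTC133 and 4.5 against 0.9 TPM in BHT101, a difference of -3.18 on the log2 scale. The unnamed noncoding gene ENSG00000281181, in ribosomal DNA with near-identical copies, was at 258.7 against 30.3 TPM in FTC133 and 33.6 against 70.7 TPM in BHT101, a difference of 4.10.

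With the SREBF1 vector, proliferation genes had a median log2 change of -0.71 in K1 (34 of 36 below 0) and 0.35 in 8505C (35 of 36 above 0), a difference of -1.06. MYBL2 was at 3.62 against 16.7 TPM in K1 and 134.3 against 75.0 TPM in 8505C. Interferon response genes differed by 0.411 (0.18 in K1, -0.23 in 8505C), TGF-beta targets by 0.453 (0.25 and -0.20) and replication-dependent histones by 1.47 (0.15 and -1.32). Histone messages mostly lack poly(A) tails, and the means of RNA selection is not given in the sources used here.

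Single genes with opposite changes of at least 2-fold between the vector lines, chosen after their values were seen among genes with at least 100 recovered reads, were these, as log2 change in K1 minus that in 8505C. The arginine transporter gene SLC7A2 differed by -2.27 (206 against 473 TPM in K1, 12.2 against 5.2 TPM in 8505C). The basement membrane gene NID2 differed by -3.96 (62.6 against 153 and 22.4 against 2.6 TPM). SRPX2 differed by -2.01 (4.4 against 9.8 and 130.8 against 64.7 TPM), CORO2B by 2.49 (18.6 against 8.6 and 7.4 against 22.0 TPM) and FGFBP1 by 2.67 (162 against 74.3 and 8.1 against 25.8 TPM). IGFBP3 differed by 4.85 (319.8 against 30.3 and 199.9 against 564.3 TPM). RN7SL1, a signal recognition particle RNA with many near-identical copies, differed by 3.01 (325 against 109 and 22.1 against 61.5 TPM).

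The lower NF-kB and inflammatory genes with the SREBF1 vector were weighed against technical explanations. After removing a trend with GC content, length and expression within each line, the median nearest to 0 was still -0.629 (K1, bootstrap interval -0.96 to -0.28), and 8505C was at -1.19. A loss of 1 chromosomal region was argued against by the 19 members outside chromosome 4, on 12 other chromosomes, whose median was -0.522 in K1 (bootstrap interval -1.01 to -0.33) and -1.28 in 8505C. Haematopoietic cells in the empty vector cultures were argued against because at most 3 of 16 haematopoietic markers exceeded 1 TPM in an empty vector library, with PTPRC at 0.633 and LYZ at 0 TPM in the K1 library that held 4621 TPM of IL1B, and CORO1A and CD68 at 0.119 and 0.0895 TPM there, although such cells hold these transcripts in abundance. The 8505C library had PTPRC at 0.0535 and LYZ at 0 TPM. Markers above 1 TPM did go with the pattern in part, CD14 at 15.3 against 47.1 TPM in K1 and 13.2 against 22.3 TPM in 8505C and LCP1 at 17.1 against 76.6 TPM in K1, whereas CSF1R was at 1.59 against 1.39 TPM in K1. An effect of SREBF1 itself was not tested apart from the culture, since density, medium or stress of the single cultures is confounded with the vector, and both stay open.

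The higher interferon response genes with SREBF1 siRNA in FTC133 were not removed by the trend correction, which left a median of 0.935 (bootstrap interval 0.77 to 1.19). Both FTC133 libraries carried an siRNA, so a response to siRNA would have to differ between the control and the SREBF1 siRNA. A response to the SREBF1 siRNA itself predicts a rise in any line that senses it, and BHT101 had a median of 0.0750, within its random range. That value does not decide, since lines differ in how they sense RNA and the siRNA sequences are not given in the sources used here. This explanation, an effect of lower SREBF1 and the state of the single cultures cannot be told apart.

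The higher cholesterol genes with SREBF1 siRNA in BHT101 were likewise not removed by the trend correction, which left a median of 0.501 (bootstrap interval 0.33 to 0.68). A compensating rise of SREBF2 could contribute, and its message was at a ratio of 1.12. In K1, however, SREBF2 was also higher with the vector, and cholesterol genes had a median of -0.155 there, within their random range. The message therefore does not decide, and the activity of the SREBF2 protein was not measured here. This candidate explanation cannot be told apart from a direct effect of the siRNA or from a difference in medium sterols between the cultures.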

How the results depend on the processing

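The settings of at least 100 recovered reads, protein-coding genes and voom were chosen after seeing the data. Gene counts of 0 held for silencing and the difference contrast under every setting run, and the fit without the cell line block or pairing also called 0 genes in each contrast. For silencing the count by voom was 0 narrowly (smallest adjusted p = 0.05985). Overexpression gave 2 genes with at least 100 recovered reads and 10 by voom, and the 4-line comparison 1 by voom; the cause was not tested. Lists past camera with the preset correlation (8, 7 and 11 for silencing, overexpression and 4 lines) became 0, 0 and 0 both with an estimated correlation and with fry. Both alternatives rest on the few residual degrees of freedom of the fit and have little power. The loss of every list therefore does not decide whether the lists changed. Leaving out a line gave 4 to 11, 4 to 7 and 7 to 14 lists, from fewer samples; for a single experiment the lone pair left is assumed to vary like the lines of the other. Genes changed at least 2-fold, in the order BHT101, FTC133, 8505C and K1, numbered 2510, 2958, 3542 and 3253 with a pseudocount of 0.1, 233, 361, 511 and 444 with 5, 2209, 2801, 3164 and 2829 with no filter, and 298, 534, 717 and 570 with a mean TPM of at least 5. They numbered 60, 216, 283 and 222 with at least 100 recovered reads, and 136, 387, 581 and 440 among protein-coding genes. These counts fell where low values were damped or left out and rose where they were kept or weighted more, and read depth as a reason was not tested.

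Lists turned direction when a line was left out. Over the lines left out, the silencing median ranged from -0.058 to 0.52 for cholesterol genes, -0.0505 to 0.63 for the stress response, -0.11 to 0.35 for MAPK output and -0.0493 to 0.79 for hypoxia targets. The overexpression median ranged from -1.31 to 0.15 for histones and -0.71 to 0.35 for proliferation, and the 4-line median from -0.20 to 0.15 for the stress response. At 0.15, without BHT101, the stress response gained a call in camera with the preset correlation (adjusted p = 0.00615). The 4-line median for histones ranged from -0.44 to -0.0048, below 0 throughout, and only its direction in camera turned, without a call (adjusted p = 0.415 without 8505C). Single genes stayed without a call in 4885 comparisons, in which direction was not compared, and gained a call in 5. Of the list comparisons, 984 were the same, 92 lost a call, 44 gained 1 and 8 reversed.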

Other observations

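Of the marker lists of other cell types and of the thyroid lineage, only fibroblast markers passed camera in either experiment, higher with silencing, and not with an estimated correlation (adjusted p = 0.748) or without BHT101 (0.39). With SREBF1 siRNA, mesenchymal markers had a median log2 change of 0.13 (17 of 27 above 0, camera adjusted p = 0.452) and epithelial markers -0.12 (14 of 23 below 0, 0.0967), with epithelial markers at -0.41 in BHT101 (20 of 23 below 0, random lists -0.07 to 0.12) and 0.13 in FTC133, within its range. Mesenchymal markers lay above their random ranges in both siRNA lines, at 0.15 in BHT101 (random lists -0.05 to 0.11) and 0.20 in FTC133 (-0.20 to 0.08). Thyroid differentiation genes were at 0.15 (0.699), and PAX8 was at 45.3 against 61.3 TPM in FTC133 and 1.28 against 1.39 TPM in BHT101. Endothelial markers were at 0.09 (0.452). With the vector, mesenchymal markers were at -0.08 (0.412), though the collagenase gene MMP1 was at 55.5 against 295.4 TPM in K1 and the fibronectin gene FN1 at 592.1 against 1621 TPM in 8505C. Epithelial markers were at -0.20 (0.412), with K1 at -0.19 just below its random range (-0.17 to 0.08), thyroid differentiation genes at 0.02 (0.955), fibroblast markers at -0.13 (0.427) and endothelial markers at -0.25 (0.427). Among fibroblast markers, PDPN was at 4.69 against 56.3 TPM and POSTN at 5.96 against 55.0 TPM in 8505C. Of 16 haematopoietic markers 4 passed the filter on mean TPM, too few for the test, with LCP1 at 17.1 against 76.6 TPM in K1.

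Further metabolic and signalling lists did not pass camera in either experiment. SREBP pathway genes had medians of 0.04 with silencing (adjusted p = 0.563) and 0.09 with overexpression (0.412), LXR targets 0.15 (0.306) and -0.07 (0.621), Hippo core components -0.05 (0.458) and -0.08 (0.412), fatty acid oxidation genes -0.02 (0.186) and -0.07 (0.462), p53 targets -0.01 (0.558) and 0.03 (0.698), TGF-beta targets 0.15 (0.0618) and -0.01 (0.881), and ferroptosis and antioxidant genes -0.02 (0.919) and -0.17 (0.154). TGF-beta targets lay above their random ranges in both siRNA lines, at 0.17 in BHT101 (random lists -0.06 to 0.14) and 0.29 in FTC133 (-0.23 to 0.10). They were also above it with the vector in K1 (0.25). NF-kB and inflammatory genes, lower with the vector, were at 0.26 with silencing (21 of 26 above 0, 0.0618), with 0.38 in BHT101 and -0.07 in FTC133, inside its random range, so only 1 siRNA line was higher. Proliferation genes were at -0.10 with silencing (31 of 36 below 0, 0.0533) and mitochondrially encoded genes at 0.18 with overexpression (13 of 13 above 0, 0.0541). Only FTC133 had lower proliferation genes (31 of 36 below 0, median -0.28). In BHT101 19 of 36 were above 0 (median 0.04, inside its random range). Over the 4 lines mitochondrially encoded genes passed (12 of 13 above 0, median 0.13, 0.0284), with an adjusted p of 0.579 with an estimated correlation. They did not pass whichever line was left out (0.139 to 0.362), with medians from 0.08 without K1 to 0.14 without 8505C. Apolipoprotein E (APOE) was at 33.0 against 21.5 TPM in BHT101 and 131.9 against 43.7 TPM in FTC133 with the siRNA. The lysosomal precursor gene PSAP was at 1541 against 1079 TPM in 8505C and 1281 against 632.2 TPM in K1 with the vector.

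Other assignments of the treated label within lines were run after the result had been seen. All 8 of the 8 splits that part every cell line gave as many genes called as the real one, which is 0, with 930 genes at an unadjusted p under 0.05 in the real split and 990 in the highest other. The splits are too few for a share under 0.05, and with 0 genes called in the real split no other can call fewer, so the count does not bear on chance.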
